A study of Arabidopsis thaliana with 12 samples.

How the data were processed

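Transcript levels were measured in whole plants of Arabidopsis thaliana, ecotype Columbia, of 2 genotypes: the hda6 mutant axe1-5, which carries a mutant allele of the histone deacetylase gene HDA6, and its parental line DR5. Per the labels, 14-day-old plants grown on agar medium with 1% sucrose under 16 h of light and 8 h of darkness were either left untreated or kept for 3 days at 2 °C under 12 h of light and 12 h of darkness. Each of the 4 groups had 3 independent biological samples, and each sample was hybridised to its own one-colour array, which gives 12 arrays. Groups and replicate numbers were taken from the sample titles.

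Per the labels' protocols, Cy3-labelled cRNA was made from 0.5 ug of total RNA with the Quick Amp kit. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 9.1.3.1 under a one-colour gene expression protocol, which subtracted the background and corrected spatial trends. The deposited intensity values of each spot are the processed signal, the mean signal and the median of the local background, none of them normalized between arrays by the authors. The deposited files also give other marks per spot, per the file headers: whether it was well above background, saturated or an outlier in its pixels or among replicate spots. The authors' table of processed values was compared with the scanner files: it held, on a linear scale, a ratio of each processed signal to the 75th percentile of its array for 43553 probes, with a floor at 0.01 that held between 27.4% and 29.7% of the values of an array. Its column medians ran from 0.149 to 0.185. The deposited table has no centring of genes and no direction to settle, and it was used as an alternative source of values. The genome build behind the probes is not given in the sources used here.

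Each array held 45220 spots, 43803 of which were not controls and covered 43603 probes, 50 of them with several spots. The main values were log2 of the processed signal minus the 75th percentile of log2 signal on the same array. Spots marked as outliers were left out, saturated spots were kept, and spots of one probe were averaged. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which kept 32526 probes. A locus was named from the annotation columns of the scanner files, by the systematic name for 38613 spots and by the gene name for another 644, and 4546 spots had no locus. Of the 29043 loci on the array, 28608 were found in a reference gene table of the TAIR10.1 assembly, which was used for names and for the order of neighbouring genes. Descriptions from the array design can be old. A gene was represented by its brightest kept probe over all 12 arrays, and where its other kept probes moved the opposite way this is stated. This gave 22139 genes, 15 of which had no value in one of the groups after outliers were left out, so 22124 genes were tested.

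Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, so that the groups shared one estimate of the spread with 8 residual and 1.88 prior degrees of freedom. The 5 comparisons were the cold response in each genotype, the difference between axe1-5 and DR5 in each condition, and the difference between the 2 cold responses. A gene was called where its moderated limma test gave a Benjamini-Hochberg adjusted p below 0.05. Counts of at least 2-fold use bounds for genes near background unless stated. Files were read with fread of the R package data.table, version 1.17.8. A gene not well above background on any array of a group, or saturated on all of them, has only a bound there. The bound sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's own level and the lowest level among probes well above background. Between 30771 and 32626 probes per array were well above background (70.6% to 74.8%), the median signal of an array was 576 to 807, and 1 to 12 spots per array were saturated. The number of arrays limits the precision of every value.

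Before the data were examined, the groups, the tests, the alternatives, 21 gene lists and the rule for naming genes were fixed. By that rule each comparison names HDA6, the 6 called genes with the largest rise and the 6 with the largest fall among those well above background on every array and with groups that did not overlap, the 3 largest bounds in each direction, up to 3 called members of each list by size of change, and the members of the lists of cold transcription factors and of silenced loci. Of the list members that the rule names, the text gives part as examples. The lists held 288 different loci besides the transposable element genes, 2 of which were not on the array, and 270 were tested. The transposable element list was taken from the annotation, with 200 genes tested of 1237 loci on the array. Shifts of lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over the 105 tests of 21 lists in 5 comparisons. Counts of called members are given over all genes tested and, where stated, adjusted over the list alone. In 15 of the 105 tests the median, the mean and the camera test of a list differed in sign, and 0 of these passed the threshold.

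Before use, the fits were tested on simulated data with the real genes and known changes. Of 100 genes changed 2-fold, 89% were recovered for the cold response in DR5, 88% for that in axe1-5, 90% for each genotype comparison and 73% for the difference of the cold responses, and of 100 genes changed 1.5-fold 61%, 66%, 64%, 64% and 54% in the same order. Of the 22124 genes simulated, 5, 5, 10, 8 and 6 unchanged ones were called. A simulated shift of 1 list was called with 0 other lists. Genes were drawn independently of each other, so this does not show how the list test behaves where listed genes are correlated. Far fewer genes were changed in the simulation than the real cold comparisons called, so recovery there can differ.

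The alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the array median, no filter on dim probes or a filter on all 12 arrays, the mean of a gene's probes, the authors' processed values, the replicate number as a block, the slide as a random block, an intensity trend in the variance, a fit to only the 2 groups compared, an adjusted p below 0.01, and leaving out each of the 12 arrays in turn. The arrays lay on 3 slides that were scanned on 1 day. Each slide held 1 array of every group and the slides coincide with the replicate numbers, so the slide and the replicate number are 1 block. Calls rest on the same arrays, so agreement in direction across the slides is largely fixed for called genes. It is given as a description and is no separate support. Groups also kept one position each on the slides, so position and group cannot be told apart. Left out were control spots, spots marked as outliers and, from counts of genes, probes without a locus.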

Results

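The 12 arrays measured transcript levels in whole plants, untreated or cold-treated, of the parental line DR5 and of axe1-5, an hda6 mutant. Each of the 4 groups had 3 biological replicates. The comparisons ask how the transcriptome responds to 3 days at 2 °C, how it differs in plants mutant for the histone deacetylase HDA6, and whether the mutant responds to cold in another way. Replicates of a group correlated at 0.991 to 0.996 over all genes tested, and no pair of arrays held identical values. The first principal component, with 78.8% of the variance, separated cold from untreated plants, and the second, with 14.5%, separated the genotypes. DR5 untreated replicate 1 stood apart on the third component, which held 1.78% of the variance, at 34.0 against -1.87 and 6.98 for the other DR5 untreated arrays. Plants sampled after cold were 3 days older and had been under a shorter light period, so temperature, age and day length changed together. The time of day of sampling is not given in the sources used here.

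HDA6 (AT5G63110), the gene mutated in axe1-5, had nearly the same level in untreated plants of both genotypes. On the log2 scale, relative to the 75th percentile of each array, the level was -0.46 ± 0.02 (SD, n = 3) in untreated DR5 and -0.54 ± 0.05 in untreated axe1-5. The difference of -0.084 did not pass the test (adjusted p = 0.591). Cold raised HDA6 by 1.38 ± 0.10 (log2 ± SE) in DR5 and by 0.37 ± 0.10 in axe1-5, with adjusted p = 2.25e-07 and adjusted p = 0.00445. The rise in axe1-5 was 0.24 without axe1-5 cold replicate 3 and 0.58 when arrays were centred on their medians. After cold the level was therefore lower in axe1-5 by a log2 difference of -1.10 ± 0.10 (adjusted p = 3.9e-05). The difference between the cold responses was -1.01 ± 0.14 (adjusted p = 0.00897), in the same direction on all 3 slides. A second HDA6 probe was not well above background on any of the 12 arrays. A transcript level cannot check the genotype labels here, since the nature of the axe1-5 allele is not given in the labels.

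**Figure D1:**
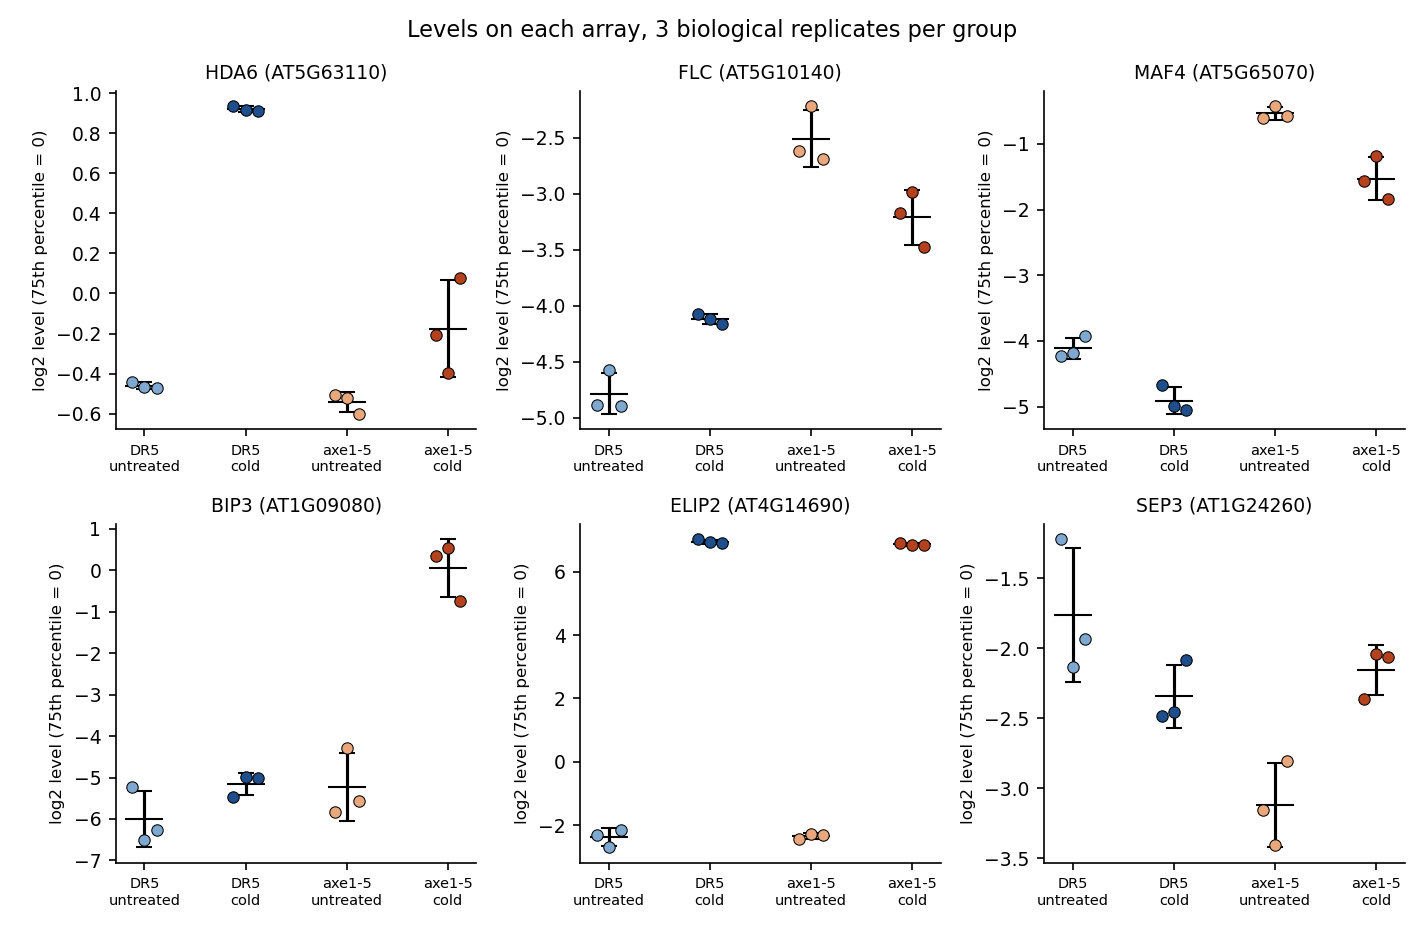
Log2 levels of HDA6, FLC, MAF4, BIP3, ELIP2 and SEP3 on each of the 12 arrays (points, 3 biological replicates per group), with the mean (bar) and SD (whiskers) of each group and 0 at the 75th percentile of the array. HDA6 levels after cold lay lower in axe1-5 (mean -0.18) than in DR5 (mean 0.92), while BIP3 was highest in cold-treated axe1-5.

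With 3 days of cold in DR5, ELIP2 (AT4G14690), an early light-induced protein of the thylakoid, rose by 9.34 ± 0.12 (log2 ± SE, n = 3 arrays per group). The late embryogenesis abundant gene AT3G17520 rose by 7.99 ± 0.52, and GPT2 (AT1G61800), a plastid glucose 6-phosphate translocator, by 7.67 ± 0.24. The glycosyltransferase gene AT2G22590 rose by 7.21 ± 0.10 and the transporter gene AT1G04570 by 7.21 ± 0.08. ELIP1 (AT3G22840) rose at least 163-fold, a bound because its probe was saturated on the cold arrays. The gibberellin-regulated gene GASA6 (AT1G74670) changed by -9.74 ± 0.16, the RING finger gene AT5G22920 by -7.46 ± 0.10 and the beta-xylosidase gene BXL1 (AT5G49360) by -7.42 ± 0.20. Changes of the expansin gene EXPA8 (AT2G40610), AT4G27450 and MLP329 (AT2G01530) were -6.68 ± 0.26, -6.67 ± 0.15 and -6.58 ± 0.30. Among genes not well above background in untreated plants, the flavonol glycosyltransferase gene UGT78D3 (AT5G17030) rose at least 304-fold, AT4G27360 at least 240.4-fold and the Dof-type zinc finger gene AT1G26790 at least 167-fold. Among genes not well above background after cold, the ERF-family gene ORA47 (AT1G74930) was at least 234-fold lower, AT4G20820 at least 70.6-fold and the jacalin lectin gene AT1G52100 at least 61.4-fold lower. The adjusted p of these genes lay between 7.27e-12 and 1.39e-07.

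Of the 19 cold-regulated protection genes in DR5, 16 rose and 3 fell, with the dehydrin gene LTI30 at 4.41 ± 0.09 and COR15A at 3.13. The camera test gave adjusted p = 0.000762 at the preset correlation and adjusted p = 0.831 with an estimated correlation. All 16 flavonoid and anthocyanin genes rose, with a median of 3.86, or 3.76 with dim genes at their bounds (adjusted p = 1.09e-06, and adjusted p = 0.22 with an estimated correlation). Among them chalcone synthase (CHS) rose by 5.70 ± 0.06, chalcone isomerase (CHI) by 5.22 ± 0.09 and F3H by 5.15 ± 0.06. All 11 ribosome biogenesis genes rose as well, with the fibrillarin gene FIB2 at 2.97 ± 0.13 and NOP56 at 2.65 ± 0.11 (adjusted p = 5.82e-05, and adjusted p = 0.474 with an estimated correlation). Of 14 sugar and proline genes 12 rose (adjusted p = 0.000762, and adjusted p = 0.404 with an estimated correlation). The sucrose synthase gene SUS1 at 4.46 ± 0.14 and the plastid beta-amylase gene BAM3 at 3.74 ± 0.07 led those well above background on every array. Adjusted over the list alone, the counts of these lists were the same except for 1 lower sugar and proline gene. Of the 14 cold transcription factors 6 rose and 4 fell over all genes and adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.648). RAP2.1 rose by 3.51 ± 0.07, RAP2.6 by 2.01 ± 0.25, ZAT12 by 1.71 ± 0.09, CBF3 by 0.72 ± 0.16 and ICE1 by 0.67 ± 0.07. Among the falls, CBF1, one of the 3 C-repeat binding factors, changed by -4.27 ± 0.29, ZAT10 by -1.22, DREB2A by -0.94 and CAMTA3 by -0.68 (-0.45 when arrays were centred on their medians). CBF2 rose by 0.65 ± 0.25 (adjusted p = 0.0335). That call ended without DR5 untreated replicate 1, where the value was 0.29 (adjusted p = 0.0547), without DR5 cold replicate 1, 2 or 3 (adjusted p = 0.0605, 0.0863 and 0.0583) and in a fit of the 2 groups alone (adjusted p = 0.1). The values for CZF1 (-0.05), DEAR1 (-0.13), MYB15 (0.22) and RAV1 (0.25) did not pass, and the first pair turned to 0.18 and 0.10 when arrays were centred on their medians.

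The lists of cell cycle and growth, photosynthesis and jasmonate response had more lower than higher members in DR5. Of 13 cell cycle and growth genes 12 fell, with the expansin EXPA1 at -2.62 ± 0.10 and the cyclin CYCB2-4 at -1.98 ± 0.09 (camera adjusted p = 0.00509, and adjusted p = 0.846 with an estimated correlation). Of 21 photosynthesis genes 13 fell and 1 rose, against 12 and 7 when arrays were centred on their medians (adjusted p = 0.00844, and adjusted p = 0.858 with an estimated correlation). LHCB4.2 was at -3.81 ± 0.07 and LHCA4 at -2.68 ± 0.06. Of 18 jasmonate genes 12 fell, among them the storage protein genes VSP2 at -3.01 ± 0.24 and VSP1 at -2.84 ± 0.26 (adjusted p = 0.0261, and adjusted p = 0.846 with an estimated correlation). This list did not pass without DR5 untreated replicate 1 (adjusted p = 0.0563). The lists that follow did not pass as a whole. In the ABA list 10 of 18 rose and 4 fell (RD29B 4.91 ± 0.43, ADH1 4.81 ± 0.18, HAI1 -3.37 ± 0.24, list adjusted p = 0.21). In the clock list 7 of 14 rose and 6 fell (CCA1 5.80 ± 0.12, LHY 5.76 ± 0.19, PRR9 4.84 ± 0.11, list adjusted p = 0.533). Clock transcripts cycle over the day, and the time of day of sampling is not known here. In the salicylate list 2 of 11 rose and 5 fell (PR5 3.47 ± 0.48, EDS1 -1.18 ± 0.04, list adjusted p = 0.66). In the auxin list 1 of 13 rose and 9 fell (SAUR15 -3.59 ± 0.20, or -2.25 with normexp, GH3.5 -2.39 ± 0.12, list adjusted p = 0.163). VIN3, which acts in vernalization, rose at least 28.7-fold from a level not well above background, TSF at least 4.41-fold and SOC1 by 1.11 ± 0.11. Of 16 flowering time genes 7 rose and 5 fell (list adjusted p = 0.781). Of 16 histone deacetylase genes 9 rose and 5 fell (HDT4 2.30 ± 0.09, HDT1 1.99 ± 0.10, list adjusted p = 0.163). Of 16 genes of DNA methylation and silencing 3 rose and 11 fell (DCL3 -1.52 ± 0.07, NRPE1 -1.33 ± 0.09, ROS1 -1.26 ± 0.16, list adjusted p = 0.107). In the heat shock list 4 of 9 rose and 2 fell (HSP70 2.71 ± 0.16, list adjusted p = 0.604). The counts of these 11 lists were unchanged when adjusted over the list alone. With arrays centred on their medians 2 ABA and 3 salicylate genes fell and 3 auxin genes rose.

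Of 10 root markers 5 rose and 4 fell (NRT2.1 5.13 ± 0.39, well above background on 2 of 3 untreated arrays, and CASP1 -2.13 ± 0.23, list adjusted p = 0.799). Of 5 seed maturation markers 2 rose (OLEO4 0.82 ± 0.12, list adjusted p = 0.533). Of the 7 floral organ genes 3 fell over all genes and 1 adjusted over the list alone, and also 1 with quantile normalization or median centring (PI -1.08 ± 0.17, list adjusted p = 0.533). SEP1 at -0.79 was no longer called without DR5 untreated replicate 2 (-0.53, adjusted p = 0.107) or DR5 cold replicate 2 (adjusted p = 0.09), with quantile normalization (-0.51, adjusted p = 0.136) or with median centring (adjusted p = 0.0973). SEP3 at -0.58 (adjusted p = 0.0414) was no longer called without DR5 untreated replicate 1 (-0.31, adjusted p = 0.158), DR5 cold replicate 1 or 2 (adjusted p = 0.114 and 0.107), axe1-5 untreated replicate 1 (adjusted p = 0.0544) or axe1-5 cold replicate 2 or 3 (adjusted p = 0.0514 and 0.0522). SEP3 also lost its call with quantile normalization (adjusted p = 0.145), median centring (-0.35, adjusted p = 0.176), no filter on dim probes (adjusted p = 0.0598) or a fit of the 2 groups alone (adjusted p = 0.0768). Of 200 transposable element genes 70 rose and 37 fell, and 68 and 33 adjusted over the list alone (AT1G65485 at least 24.8-fold and AT5G52055 at least 9.80-fold higher, AT1G35612 -3.31 ± 0.11, list adjusted p = 0.296). Of 9 measured silenced or developmentally repressed loci 2 rose and 5 fell, also adjusted over the list alone (list adjusted p = 0.538). Among these, KNAT1 was at 1.33 ± 0.09, FLC at 0.67 ± 0.15, MAF4 at -0.80 ± 0.16 and KNAT2 at -0.98 ± 0.10. With quantile normalization the last pair was at -0.43 and -0.65. FUS3 fell at least 1.69-fold to a level not well above background, a call that normexp (adjusted p = 0.525) and the authors' processed values (adjusted p = 0.507) did not give. KNATM fell at least 1.70-fold from a level well above background on 2 of 3 arrays, a call that the authors' processed values did not give (adjusted p = 0.183). SDC passed as well (adjusted p = 0.000249), but it was not well above background on any DR5 array and has no fold there. Neither normexp (adjusted p = 0.211) nor the authors' processed values (adjusted p = 1) gave this call. MAF5 at -0.93 did not pass (adjusted p = 0.0738), and AtMu1, not well above background on any DR5 array, did not pass (adjusted p = 0.924).

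Altogether 18452 of 22124 genes changed with cold in DR5, 9036 higher and 9416 lower, and 7700 of them at least 2-fold (3402 higher and 4298 lower). At an unadjusted p below 0.05 the number was 18606. Of the calls, 98.6% (18200) had the same direction on each of the 3 slides. With the slide as a block 18587 genes were called. Centring on array medians moved the median of all genes by 0.23, and the split became 10914 higher and 7547 lower, 59.1% against 49.0%. Quantile normalization gave 9604 higher and 8777 lower.

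With cold in axe1-5, ELIP2 rose by 9.21 ± 0.12, GPT2 by 8.88 ± 0.24, AT1G04570 by 6.82 ± 0.08 and AT2G22590 by 6.52 ± 0.10, AT3G09450 by 9.38 ± 0.12, and ELIP1, again saturated after cold, at least 158-fold. GASA6 was at -9.73 ± 0.16, AT5G22920 at -7.29 ± 0.10, BXL1 at -7.11 ± 0.20, the J-domain gene J8 (AT1G80920) at -6.42 ± 0.09, AT4G27450 at -6.38 ± 0.15 and EXPA8 at -6.32 ± 0.26. Starting from a level not well above background, UGT78D3 rose at least 369-fold, AT1G26790 at least 166-fold and AT4G27360 at least 158.5-fold. ORA47 was at least 262-fold, AT1G52100 at least 102-fold and P1R3 (AT3G29370) at least 94.3-fold lower. The adjusted p of these genes lay between 7.39e-12 and 6e-09.

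In axe1-5, 7 lists passed the camera test. All 16 flavonoid genes rose, with a median of 4.04, or 3.96 with dim genes at their bounds (CHS 5.58 ± 0.06, CHI 5.47 ± 0.09, adjusted p = 1.07e-06, and adjusted p = 0.22 with an estimated correlation). All 11 ribosome biogenesis genes rose here too (FIB2 3.06 ± 0.13, adjusted p = 5.82e-05, and adjusted p = 0.474 with an estimated correlation). Of 19 cold-regulated protection genes 15 rose and 3 fell (LTI30 3.99 ± 0.09, COR15A 2.72, adjusted p = 0.00192, and adjusted p = 0.831 with an estimated correlation). Of 14 sugar and proline genes 12 were higher (SUS1 4.15 ± 0.14, BAM3 3.82 ± 0.07, adjusted p = 0.00146, and adjusted p = 0.436 with an estimated correlation). Photosynthesis had 14 of 21 genes lower and 1 higher, 12 and 4 when arrays were centred on their medians (LHCB4.2 -3.83 ± 0.07, adjusted p = 0.00321, and adjusted p = 0.846 with an estimated correlation). The cell cycle and growth list had 11 of 13 lower and 1 higher (EXPA1 -3.24 ± 0.10, adjusted p = 0.011, and adjusted p = 0.846 with an estimated correlation). The jasmonate list had 12 of 18 lower and 1 higher (JAZ5 -3.31 ± 0.34, adjusted p = 0.0396, and adjusted p = 0.846 with an estimated correlation), and it did not pass without axe1-5 cold replicate 2 (adjusted p = 0.0602). The counts of these 7 lists were the same adjusted over the list alone.

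Of the 14 cold transcription factors, 5 were higher and 8 lower in cold axe1-5, over all genes and adjusted over the list alone (list adjusted p = 0.832). CBF1 was at -5.44 ± 0.29, ZAT10 at -1.92 ± 0.18, DREB2A at -1.62 ± 0.13, MYB15 at -1.18 ± 0.36 (-0.76 without axe1-5 cold replicate 2) and CAMTA3 at -0.87 ± 0.06. RAP2.1 was at 3.52 ± 0.07, RAP2.6 at 2.31 ± 0.25, ZAT12 at 1.42 ± 0.09, ICE1 at 0.88 ± 0.07 and RAV1 at 0.70 ± 0.14. CBF3 at -0.27 ± 0.16 did not pass (adjusted p = 0.142). CBF2 at -0.69 ± 0.25 (adjusted p = 0.0266), CZF1 at -0.41 and DEAR1 at -0.36 were no longer called with median centring (adjusted p = 0.105, 0.239 and 0.33), where CZF1 was at -0.21 and DEAR1 at -0.15. CBF2 also lost its call without axe1-5 untreated replicate 1 or 2 (adjusted p = 0.0701 and 0.0524) or axe1-5 cold replicate 1 (adjusted p = 0.0808). CZF1 lost it without axe1-5 untreated replicate 1 (adjusted p = 0.108) or axe1-5 cold replicate 2 or 3 (adjusted p = 0.0772 and 0.0778), and DEAR1 lost it without axe1-5 untreated replicate 1 or 2 (adjusted p = 0.0865 and 0.102) or axe1-5 cold replicate 2 or 3 (adjusted p = 0.0642 and 0.0873).

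The remaining lists had members called both ways in axe1-5 and no list test that passed. Counts of higher and lower members were 8 and 6 of 18 for ABA (ADH1 4.77 ± 0.18, HAI1 -3.69 ± 0.24), 7 and 6 of 14 for the clock (LHY 6.05 ± 0.19, PRR9 4.19 ± 0.11). For flowering time they were 6 and 7 of 16 (VIN3 at least 21.9-fold higher, CO 1.06 ± 0.10), and for histone deacetylases 11 and 5 of 16 (HDT4 2.36 ± 0.09). DNA methylation and silencing had 3 and 10 of 16 (DCL3 -1.43 ± 0.07, DME -1.12 ± 0.12) and salicylate 2 and 6 of 11 (PR5 5.18 ± 0.48, WRKY70 -1.58 ± 0.20). Higher and lower were 2 and 10 of 13 for auxin (GH3.5 -2.28 ± 0.12) and 6 and 1 of 9 for heat shock (HSP70 2.66 ± 0.16). Of 9 silenced loci KNAT1 was higher at 1.47 ± 0.09, and 6 were lower. The lower ones were SDC at -2.97 ± 0.25, KNAT2 at -1.04 ± 0.10, MAF4 at -0.99 ± 0.16, FUS3 at -0.85 ± 0.18 (-0.43 with normexp and -0.50 with quantile normalization), FLC at -0.70 ± 0.15 and KNATM at least 2.26-fold. MAF5 at -1.02 and AtMu1 at 0.39 were not past the test. Transposable element genes were at 66 and 57 of 200 (AT3G29572 at least 16.6-fold and AT3G31373 at least 11.4-fold higher). Root markers were at 4 and 4 of 10 (CASP1 -1.71 ± 0.23), seed markers at 2 and 1 of 5 (OLEO4 0.58 ± 0.12, or 0.90 with quantile normalization) and floral organ genes at 1 and 1 of 7 (SEP3 0.97 ± 0.24, PI -0.73 ± 0.17). Adjusted over the list alone these counts were the same, except for 62 and 55 transposable element genes. With median centring 4 flowering time genes were lower and 5 genes of DNA methylation and silencing higher. Adjusted p for these lists ran from 0.104 for auxin to 0.976 for flowering time.

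In axe1-5 the cold changed 18553 genes, 8966 higher and 9587 lower, 7755 of them at least 2-fold (3435 higher and 4320 lower). At an unadjusted p below 0.05 they were 18701. Of the calls, 99.0% (18374) had the same direction on each slide, and the slide as a block gave 18724 calls. Centring on array medians moved the median of all genes by 0.21, with 10714 higher and 7862 lower, 57.7% against 48.3%. Quantile normalization gave 9576 higher and 8919 lower.

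The cold responses of the genotypes had a Pearson correlation of 0.961 and a Spearman correlation of 0.961 across genes, which are not independent replicates. Of the calls, 8321 were higher and 8807 lower in both, where independent lists would share 3662 and 4080. The calls use one spread per gene, so they are not independent.

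**Figure D2:**
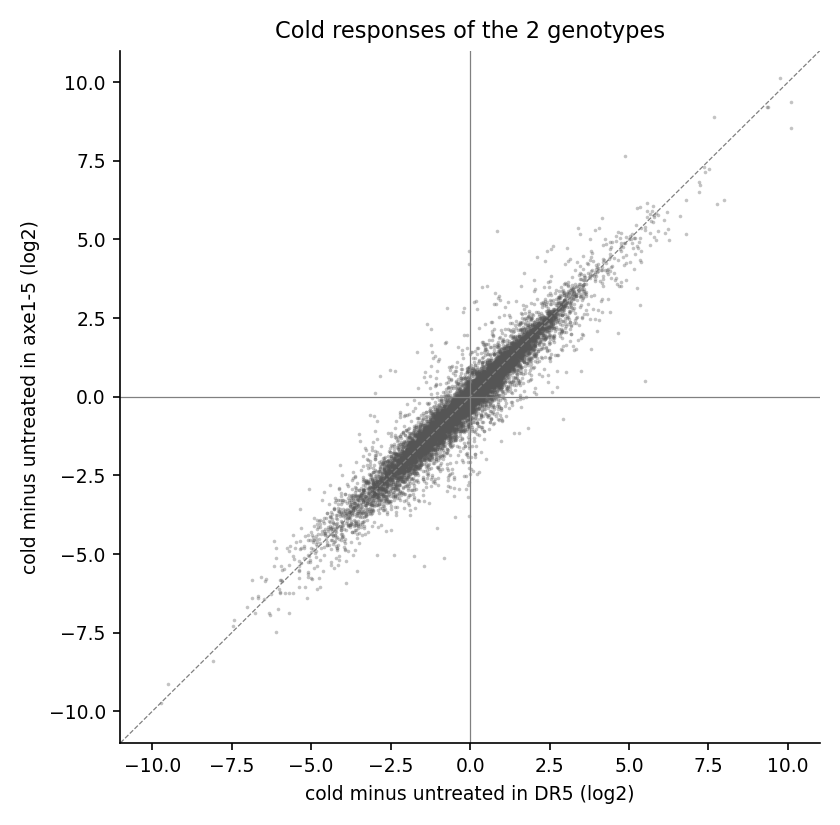
Fitted log2 change with cold in axe1-5 (vertical) against that in DR5 (horizontal) for the 22124 genes tested, 3 arrays per group, with the line of equal change dashed. Points lie along the line with a Pearson correlation of 0.961, and fitted values of genes not well above background in a group are included.

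Without cold, a set of loci had much higher transcript levels in axe1-5 than in DR5, and falls were smaller. AT4G16215 was higher by 8.99 ± 0.67 (log2 ± SE, n = 3) and AT3G54730, which is similar to an ovate family gene, by 8.99 ± 0.25. The retroelement SADHU3-2 (AT3G42658) was higher by 7.02 ± 0.53, AT5G26270 by 6.79 ± 0.15, MRD1 (AT1G53480) by 6.74 ± 0.70 and AT3G01345 by 5.49 ± 0.24. Among loci not well above background in untreated DR5, the noncoding AT2G15555 was at least 1349-fold and the transposable element genes AT5G28880 and AT1G42590 at least 507-fold and 220.3-fold higher. UGT73C6 (AT2G36790), a flavonol glucosyltransferase gene, was at -2.20 ± 0.31 (-1.20 with normexp) and GPT2 at -2.09 ± 0.24. The transcription factor gene AT1G10585 was at -2.55 ± 0.45 and the TIR-NBS-LRR gene AT4G16960 at -2.23 ± 0.08, although another probe of AT4G16960 went the opposite way and the mean of its probes gave -0.91. AT4G12735 and AT1G63055 fell to levels not well above background, at least 5.40-fold and 5.27-fold lower. The adjusted p of these genes lay between 1.65e-09 and 0.00377. AT4G12490 at -3.02 ± 0.80 was no longer called without DR5 untreated replicate 1 or 3 or without axe1-5 untreated replicate 1, 2 or 3 (adjusted p = 0.0733, 0.081, 0.0551, 0.0868 and 0.0779). The transporter gene ABCG40 at -2.28 ± 0.54 was not called without DR5 untreated replicate 1 or axe1-5 untreated replicate 1 or 3 (adjusted p = 0.0591, 0.0705 and 0.0537). A fit of the 2 groups alone also ended the call of AT4G12490 (adjusted p = 0.0754). AT2G04070 fell at least 3.20-fold (adjusted p = 0.0104), a call that the authors' processed values (adjusted p = 0.0685) and a fit of the 2 groups alone (adjusted p = 0.0593) did not give.

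Transposable element genes had the smallest list p of the 21 lists in untreated plants. Of 200 tested, 99 were higher and 8 lower in untreated axe1-5, and 108 and 9 adjusted over the list alone (camera adjusted p = 2.4e-18, and adjusted p = 0.0255 with an estimated correlation). Their median log2 difference was 0.49, or 0.37 with dim genes at their bounds. It was 0.27 with normexp, 0.28 with the authors' processed values, 0.12 without a filter on dim probes and 0.070 over probes well above background on all arrays, and the list passed each time. The number lower was 15 with quantile normalization. SADHU3-1 was at 8.46 ± 0.59 and AT3G32966 at 8.60 ± 0.63 (5.69 with normexp), each well above background on 1 of 3 untreated DR5 arrays. Of 1237 transposable element loci on the array, 111 were well above background on all 3 arrays of untreated DR5, 176 in untreated axe1-5, 119 in cold DR5 and 158 in cold axe1-5. Of 9 measured loci on the list of silenced or developmentally repressed genes 6 were higher, and 7 adjusted over the list alone, with 0 lower (adjusted p = 4.83e-05, and adjusted p = 0.197 with an estimated correlation). These were MAF4 at 3.57 ± 0.16, MAF5 at 2.30 ± 0.45, the floral repressor FLC at 2.27 ± 0.15, the embryo regulator FUS3 at 2.19 ± 0.18 (1.15 with normexp), SDC at least 21.4-fold and the Mutator-like element AtMu1 at least 9.84-fold. MAF4 and MAF5 are close relatives in sequence, so cross-hybridisation between them was not excluded. KNAT1 (-0.19), KNAT2 (-0.12) and KNATM (0.91, well above background on 2 of 3 untreated DR5 arrays) did not pass, and the other 5 listed loci were not well above background in any group.

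Floral organ genes were lower in untreated axe1-5, 5 of 7 over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00149, and adjusted p = 0.754 with an estimated correlation). Their median was -1.67, or -1.36 with dim genes at their bounds, and with normexp it was -1.10, as was AP3. SEP1 was at -1.75 ± 0.29 (adjusted p = 0.00256) and kept its call whichever array was left out. AP3 at -1.83 ± 0.44 and SEP2 at -1.67 ± 0.43 were no longer called without DR5 untreated replicate 2 (adjusted p = 0.0513 and 0.0684), DR5 untreated replicate 3 (adjusted p = 0.0599 and 0.0695), axe1-5 untreated replicate 1 (adjusted p = 0.0741 and 0.091) or axe1-5 untreated replicate 2 (adjusted p = 0.068 and 0.085). A fit of the 2 groups alone did not call them either (adjusted p = 0.0623 and 0.063). Of 10 root markers and 5 seed markers limma called 0, also adjusted over each list alone, with 1 of each at an unadjusted p below 0.05 (list adjusted p = 0.648 and 0.883).

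Of 19 cold-regulated protection genes 6 were higher in untreated axe1-5, and 10 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.00287, and adjusted p = 0.831 with an estimated correlation). The number higher was 8 with quantile normalization and 2 when arrays were centred on their medians, where the median of the list was 0.11. Without axe1-5 untreated replicate 3 the median was 0.28. COR15A was at 0.32 ± 0.06 (adjusted p = 0.00679). Among 14 cold transcription factors 4 were higher and 1 lower, and 5 and 1 adjusted over the list alone (list adjusted p = 0.163). CBF2 was at 1.3 ± 0.25 (adjusted p = 0.00664), CBF1 at 1.27 ± 0.29 (adjusted p = 0.015) and CBF3 at 0.75 ± 0.16 (adjusted p = 0.0106). CBF1 was no longer called without axe1-5 untreated replicate 1 (adjusted p = 0.06), and in a fit of the 2 groups alone neither CBF1 (adjusted p = 0.073) nor CBF3 (adjusted p = 0.0629) was. DREB2A (0.49) and ICE1 (-0.29) were also called. DREB2A lost its call without DR5 untreated replicate 1 or 3 or axe1-5 untreated replicate 1 or 2 (adjusted p = 0.0814, 0.0761, 0.0947 and 0.073), with normexp (adjusted p = 0.0663), with the mean of its probes (adjusted p = 0.0506) or in a fit of the 2 groups alone (adjusted p = 0.077). ICE1 was not called without DR5 untreated replicate 3 (adjusted p = 0.056) or axe1-5 untreated replicate 1 (adjusted p = 0.0521), nor in a fit of the 2 groups alone (adjusted p = 0.0543). The other members, ZAT12 (0.21), ZAT10 (0.50), CZF1 (0.20), RAV1 (-0.27), MYB15 (0.12), CAMTA3 (0.07), DEAR1 (0.30), RAP2.1 (0.08) and RAP2.6 (-0.15), did not pass.

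The other lists had few called members in untreated axe1-5, and their list tests did not pass. ROS1, a DNA demethylase gene, was lower at -1.29 ± 0.16 (adjusted p = 0.000377), in a list of DNA methylation and silencing genes with 1 higher and 1 lower of 16 (list adjusted p = 0.561). Of 16 histone deacetylase genes 2 were higher and 2 lower (list adjusted p = 0.533), and 2 and 6 with arrays centred on their medians. HDA18 was higher at 1.21 ± 0.15 and HDA7 at least 1.96-fold, a call of HDA7 that the authors' processed values did not give (adjusted p = 0.221). MYC2, well above background on 2 of 3 untreated DR5 arrays, was at 0.78 ± 0.12 and OPR3 at 0.55 ± 0.09. The jasmonate list had 3 higher of 18, and 4 higher and 2 lower adjusted over the list alone (list adjusted p = 0.681). GOLS1 was at 0.51 ± 0.10, with 2 higher and 1 lower of 14 sugar and proline genes (list adjusted p = 0.546). LEA14 at 0.35 ± 0.07 and ABI5 at 0.38 ± 0.08 were the 2 higher of 18 ABA genes (list adjusted p = 0.21). PRR9 was at 0.65 ± 0.11 and PRR3 at -0.39 ± 0.07, with 1 higher and 2 lower of 14 clock genes (list adjusted p = 0.446). The flowering time list, which holds FLC, MAF4 and MAF5, had 4 higher and 2 lower of 16 (list adjusted p = 0.131). The ribosome biogenesis list had 0 higher and 2 lower of 11, among them FIB1 at -0.35 ± 0.07 (list adjusted p = 0.148). Salicylate had 3 higher of 11 (adjusted p = 0.188), flavonoid 1 higher of 16 (adjusted p = 0.328) and photosynthesis 1 higher of 21 (adjusted p = 0.455). Auxin had 1 lower of 13 (adjusted p = 0.681) and heat shock 1 lower of 9 (adjusted p = 0.24). Of 13 cell cycle and growth genes limma called 0, with 1 at an unadjusted p below 0.05 (adjusted p = 0.649). The counts adjusted over the list alone were 3 higher and 1 lower for sugar and proline, 5 higher and 3 lower for flowering time and 0 for flavonoid, photosynthesis and auxin. Those of the other lists of this paragraph were unchanged. With median centring 3 genes of DNA methylation and silencing and 2 jasmonate genes were lower.

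In all, 3704 genes differed between untreated axe1-5 and DR5, 2490 higher and 1214 lower, with 742 at least 2-fold (670 higher and 72 lower). At an unadjusted p below 0.05 there were 6955. Of the 3704 called genes 99.7% (3692) had the same direction on each slide, and the slide as a block gave 3865. The count was 2302 without axe1-5 untreated replicate 1 and 2449 without DR5 untreated replicate 3. The excess of higher calls depends on the scaling. There were 2212 higher and 2019 lower under quantile normalization and 1983 higher and 3131 lower with arrays centred on their medians (52.3% and 38.8% higher, against 67.2%). Fitted changes of at least 2-fold among the called genes kept the excess, with 744 higher and 80 lower, 630 and 126 under quantile normalization and 690 and 103 with median centring.

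**Figure D3:**
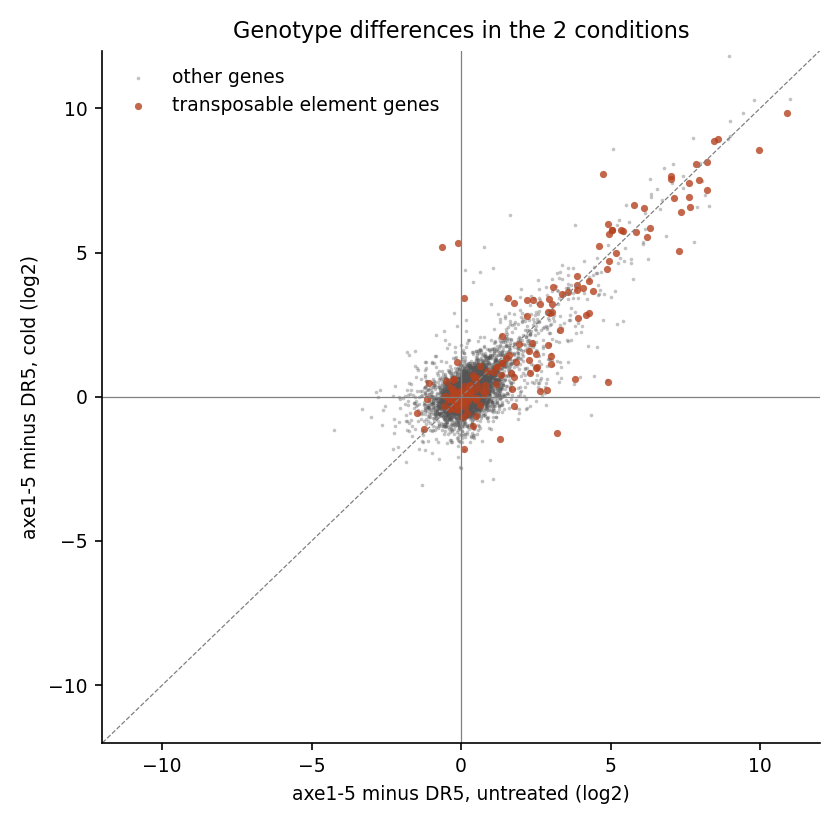
Fitted log2 difference axe1-5 minus DR5 after cold (vertical) against that in untreated plants (horizontal) for the 22124 genes tested, 3 arrays per group, with the 200 transposable element genes in red and the line of equal difference dashed. Red points spread to the upper right, 99 of them called higher in untreated and 88 in cold-treated axe1-5.

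After cold, a set of loci again had much higher levels in axe1-5 than in DR5. AT4G16215 was higher in axe1-5 by 9.06 ± 0.67, AT5G26270 by 7.93 ± 0.15, SADHU3-2 by 7.56 ± 0.53, MRD1 by 6.81 ± 0.70, AT2G05915 by 6.51 ± 0.20 and the beta-galactosidase gene AT5G01080 by 5.68 ± 0.19. From levels not well above background in cold DR5, AT4G07965 was at least 1089-fold, AT5G28880 at least 374-fold and AT5G45095 at least 308-fold higher. Lower in axe1-5 were AT3G28270 at -1.93 ± 0.39, BFT (AT5G62040), a relative of FT and TFL1, at -1.56 ± 0.24, and the jumonji gene AT1G62310 at -1.55 ± 0.08. The fatty acid desaturase gene AT1G06100 was at -1.55 ± 0.25 and TYRDC (AT4G28680), a tyrosine decarboxylase gene, at -1.49 ± 0.22. With normexp AT1G62310 was at -0.97 and TYRDC at -0.99. The adjusted p of these genes lay between 5.54e-10 and 0.0082. AT3G12850 was at least 1.57-fold lower (adjusted p = 0.00115), a call that the authors' processed values did not give (adjusted p = 0.216). AT5G39120 at least 2.15-fold lower was no longer called without DR5 cold replicate 2 or 3 or axe1-5 cold replicate 2 (adjusted p = 0.0594, 0.0637 and 0.0784) or with normexp (adjusted p = 0.131). AT5G22430 at least 2.28-fold lower lost its call without any of the 3 DR5 cold arrays (adjusted p = 0.0873, 0.0575 and 0.117), the 3 axe1-5 cold arrays (adjusted p = 0.0895, 0.086 and 0.0722) or axe1-5 untreated replicate 2 (adjusted p = 0.056). Nor was AT5G22430 called with normexp (adjusted p = 0.159), the mean of its probes (adjusted p = 0.0517) or the authors' processed values (adjusted p = 0.249). AT5G15500 at -1.57 ± 0.45 lost its call without 9 of the 12 arrays, all but DR5 untreated replicate 1, DR5 cold replicate 1 and axe1-5 cold replicate 1 (adjusted p up to 0.124), and it was at -0.99 without axe1-5 cold replicate 2. The slide as a block (adjusted p = 0.0514) and a fit of the 2 groups alone (adjusted p = 0.136) ended it as well.

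Of the 200 transposable element genes that passed the filter, 88 were higher and 5 lower, and 96 and 8 adjusted over the list alone (camera adjusted p = 2.11e-14, and adjusted p = 0.0299 with an estimated correlation). The median was 0.35, or 0.17 with dim genes at their bounds. It was 0.19 with quantile normalization, 0.14 with the authors' processed values and 0.0027 over probes well above background on all arrays, and the list passed each time. The number lower was 10 with quantile normalization and 15 with median centring. SADHU3-1 was at 8.86 ± 0.59 and AT1G42590 at 8.56 ± 0.90, each well above background on 1 of 3 cold DR5 arrays. Of 9 silenced loci 6 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00036, and adjusted p = 0.22 with an estimated correlation). Over probes well above background on all arrays the list did not pass (adjusted p = 0.0553). The 6 were MAF4 at 3.38 ± 0.16, MAF5 at 2.21 ± 0.45, FLC at 0.91 ± 0.15, AtMu1 at least 13.0-fold, FUS3 at least 4.29-fold and SDC at least 2.77-fold, the last not with the authors' processed values (adjusted p = 0.052). KNAT1 (-0.06) and KNAT2 (-0.17) did not pass, and KNATM was not well above background in either group. HDA7 was at least 5.17-fold and HDA18 by 1.58 ± 0.15 higher while HDA6 was lower, among 3 higher and 2 lower of 16 histone deacetylase genes (list adjusted p = 0.693). With median centring 4 of these were lower. ROS1 was at -1.18 ± 0.16, KYP at 0.62 ± 0.10 and NRPE1 at 0.53 ± 0.09, among 5 higher and 1 lower of 16 DNA methylation and silencing genes (list adjusted p = 0.397). With quantile normalization or median centring 3 were lower.

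Of the 19 cold-regulated protection genes limma called 0 after cold, over all genes and adjusted over the list alone, with 1 at an unadjusted p below 0.05 and a median of -0.07 (list adjusted p = 0.368). Among 14 cold transcription factors 0 were higher and 1 lower, and 0 adjusted over the list alone (list adjusted p = 0.336). That one was MYB15 at -1.28 ± 0.36 (adjusted p = 0.0354). It was no longer called without DR5 untreated replicate 3, DR5 cold replicate 2 or 3, axe1-5 untreated replicate 2 or axe1-5 cold replicate 2 or 3 (adjusted p = 0.0507, 0.108, 0.102, 0.0529, 0.0946 and 0.0857), or with the slide as a block (adjusted p = 0.0552) or in a fit of the 2 groups alone (adjusted p = 0.133). CBF1 (0.11), CBF2 (-0.04), CBF3 (-0.24), ICE1 (-0.08, with another probe in the opposite direction), ZAT12 (-0.07), ZAT10 (-0.20), CZF1 (-0.16), RAV1 (0.18), CAMTA3 (-0.13), DEAR1 (0.07), RAP2.1 (0.08), RAP2.6 (0.15) and DREB2A (-0.20) did not pass. The ABA list had 0 higher and 3 lower of 18, also adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.846 with an estimated correlation). It did not pass without DR5 cold replicate 3 (adjusted p = 0.0675) or axe1-5 cold replicate 2 (adjusted p = 0.12), with quantile normalization (adjusted p = 0.0505) or with median centring (adjusted p = 0.0941). Of these, ABF3 at -0.42 ± 0.10 (adjusted p = 0.0163) was no longer called without DR5 cold replicate 3 (adjusted p = 0.06) or in a fit of the 2 groups alone (adjusted p = 0.0769). ABI2 at -0.54 ± 0.14 (adjusted p = 0.0255) lost its call without any of the 3 DR5 cold arrays (adjusted p = 0.0532, 0.0591 and 0.0822), axe1-5 cold replicate 2 or 3 (adjusted p = 0.0962 and 0.0761) or in a fit of the 2 groups alone (adjusted p = 0.0934). RD22 at -0.67 ± 0.20 (adjusted p = 0.0431) lost its call without 9 of the 12 arrays, all but DR5 untreated replicate 1, DR5 cold replicate 1 and axe1-5 cold replicate 1 (adjusted p from 0.054 to 0.139). It was not called either with quantile normalization (adjusted p = 0.0587), no filter on dim probes (adjusted p = 0.0513), the slide as a block (adjusted p = 0.0702) or a fit of the 2 groups alone (adjusted p = 0.133). The flavonoid list had 2 higher of 16, and 5 adjusted over the list alone (F3-prime-H 0.71 ± 0.12, camera adjusted p = 0.0398, and adjusted p = 0.846 with an estimated correlation). This list did not pass without DR5 untreated replicate 1 (adjusted p = 0.0636), DR5 cold replicate 2 or 3 (adjusted p = 0.0811 and 0.0931) or axe1-5 cold replicate 3 (adjusted p = 0.0687), or without a filter on dim probes (adjusted p = 0.1).

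Other lists after cold did not pass. IAA29 was at -1.01 ± 0.20 (-0.53 with normexp), with 1 higher and 2 lower of 13 auxin genes (list adjusted p = 0.188). LHCB3 was at 0.30 ± 0.05, with 3 higher of 21 photosynthesis genes (list adjusted p = 0.533). EXPA1 at -0.47 ± 0.10 was the 1 lower of 13 cell cycle and growth genes (list adjusted p = 0.735). HSP23.6 was at 1.99 ± 0.47 (1.04 with normexp) among 2 higher of 9 heat shock genes (list adjusted p = 0.605). Its call ended without DR5 cold replicate 3 (adjusted p = 0.0589) or axe1-5 cold replicate 2 (adjusted p = 0.0575). Of 7 floral organ genes limma called 0, also adjusted over the list alone, with 2 at an unadjusted p below 0.05 and a median of -0.60 (adjusted p = 0.414). Counts higher and lower were 5 and 2 of 16 for flowering time (adjusted p = 0.336), 0 and 2 of 18 for jasmonate (adjusted p = 0.414), 1 and 1 of 11 for salicylate (adjusted p = 0.533) and 0 and 2 of 14 for the clock (adjusted p = 0.336). Of 14 sugar and proline genes limma called 0, with 3 at an unadjusted p below 0.05 (adjusted p = 0.533). Further counts higher and lower were 0 and 1 of 11 for ribosome biogenesis (adjusted p = 0.145), 0 and 1 of 5 for seed markers (adjusted p = 0.533) and 1 and 0 of 10 for root markers (adjusted p = 0.799). When adjusted over the list alone, photosynthesis had 1 higher, flowering time 5 higher and 3 lower, and ribosome biogenesis and root markers 0. The other lists of this paragraph had unchanged counts. With median centring 1 photosynthesis gene was higher and 4 ribosome biogenesis genes were lower, and with quantile normalization 5 photosynthesis genes were higher.

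After cold 3934 genes differed between the genotypes, 2562 higher and 1372 lower in axe1-5, with 601 at least 2-fold (555 higher and 46 lower). The number at an unadjusted p below 0.05 was 7071. Of them 99.0% (3896) had the same direction on each slide, and the slide as a block gave 4125. The count was 2310 without axe1-5 cold replicate 2, 2384 without DR5 cold replicate 2 and 2462 in a fit of the 2 groups alone. The split became 1839 higher and 3938 lower with arrays centred on their medians (31.8% against 65.1%). Fitted changes of at least 2-fold went from 634 higher and 69 lower to 568 and 102. Across genes, the genotype differences in the 2 conditions had a Pearson correlation of 0.803 and a Spearman correlation of 0.447. The calls shared 1336 higher and 329 lower genes, where independent lists would share 288 and 75, again with one spread per gene.

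**Figure D4:**
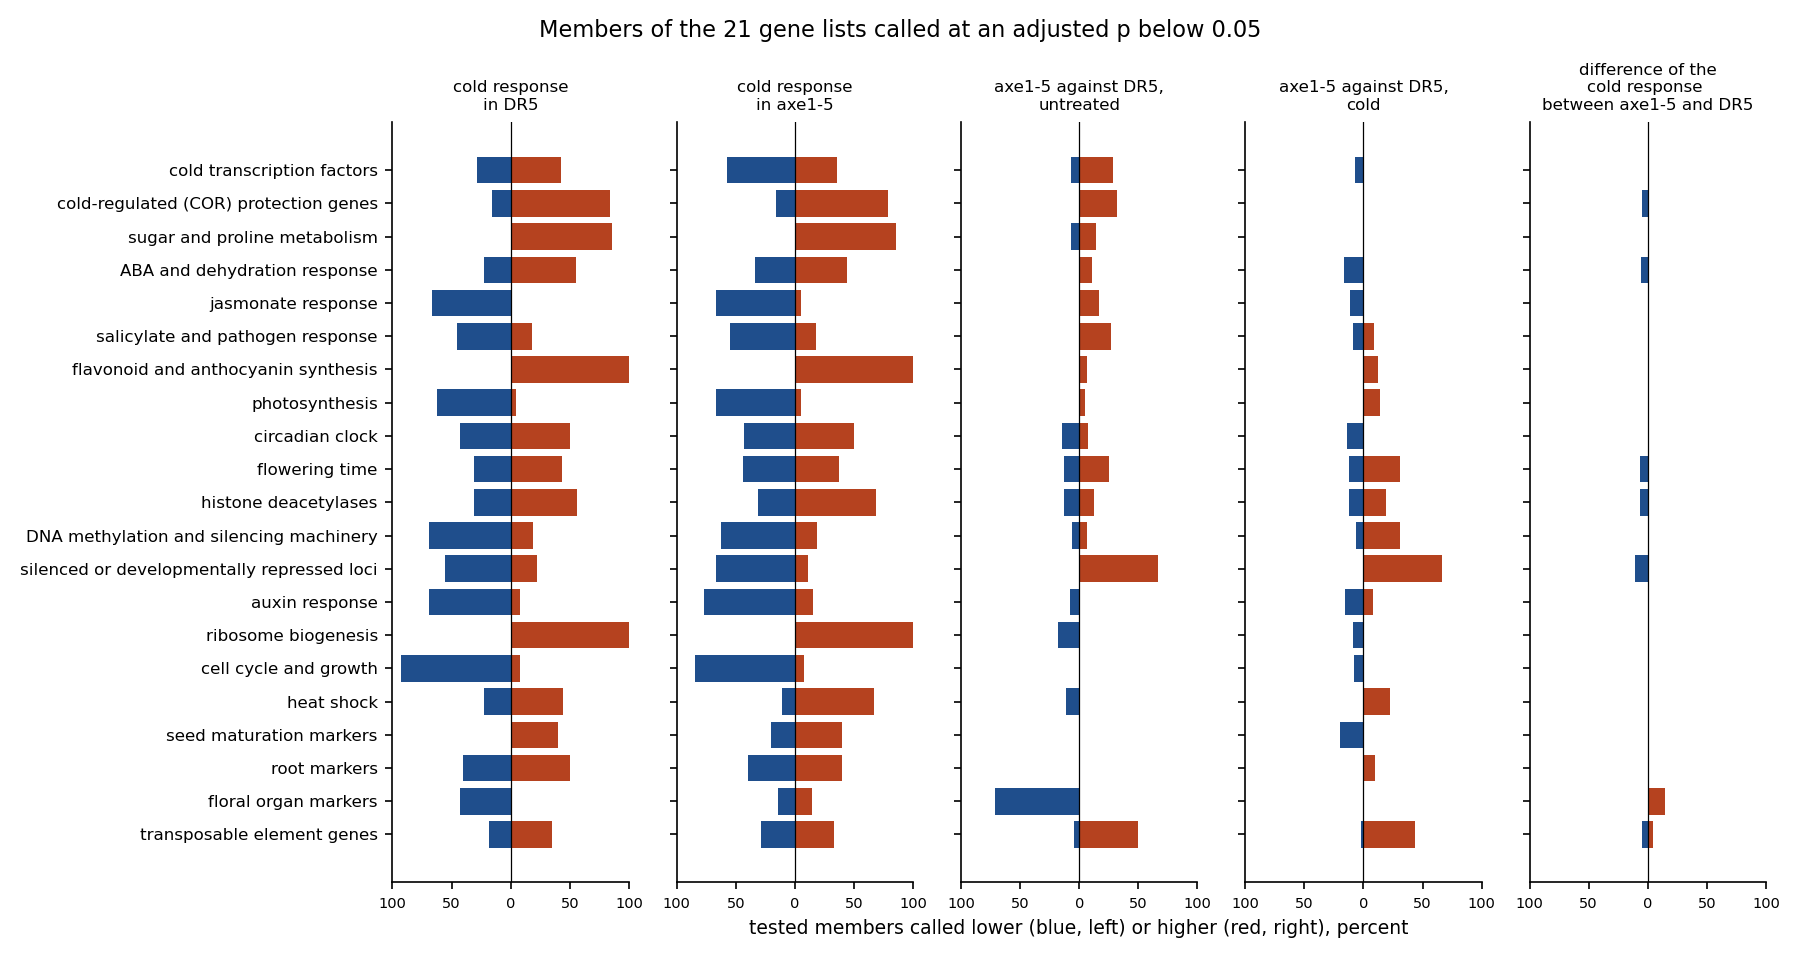
Percent of the tested members of each of the 21 gene lists called higher (red, right) or lower (blue, left) at an adjusted p below 0.05, in each of the 5 comparisons with 3 arrays per group. All 16 flavonoid genes rose with cold in both genotypes, and 99 of 200 transposable element genes were higher in untreated axe1-5.

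The test of the difference between the 2 cold responses asks which genes respond to cold in another way in the mutant. BIP3 (AT1G09080), a chaperone of the endoplasmic reticulum, changed by 0.85 with cold in DR5 and by 5.28 in axe1-5. The difference was 4.43 ± 0.68 (log2 ± SE, n = 3 arrays per group, adjusted p = 0.0153). AT4G21730, annotated as a pseudogene of an NSF gene, fell by 1.19 in DR5 and rose by 1.42 in axe1-5 (difference 2.61 ± 0.37, adjusted p = 0.0115). The oxidoreductase gene AT5G16980 fell by 1.08 and rose by 0.60 (difference 1.68 ± 0.14, adjusted p = 0.000699). In the other direction, the TIR-NBS-LRR gene AT5G41750 had a difference of -2.66 ± 0.29 (adjusted p = 0.00333) and DUF4 (AT2G46840) of -1.75 ± 0.17 (adjusted p = 0.00144), or -0.92 with normexp. FLC had a difference of -1.37 ± 0.21 (adjusted p = 0.0163), at 0.67 in DR5 and -0.70 in axe1-5. The difference for HDA6 is given above. These genes kept their call whichever array was left out, and all moved in one direction on each of the 3 slides.

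Among transposable element genes 9 of 200 had a more positive and 10 a more negative response in axe1-5, and 12 and 17 adjusted over the list alone (list adjusted p = 0.188). AT3G29572 (adjusted p = 0.00524) and AT3G31373 (adjusted p = 0.0039) were well above background only in cold axe1-5 among the 4 groups, and AT2G14970 (adjusted p = 6.39e-07) only in untreated axe1-5. The cold-regulated protection genes as a list had a lower response in axe1-5, with a median of -0.19 (camera adjusted p = 4.83e-05, and adjusted p = 0.684 with an estimated correlation). In it 1 gene, COR15A, was called, and 5 adjusted over the list alone. COR15A at -0.41 ± 0.09 (adjusted p = 0.0493) lost its call on leaving out any array but axe1-5 untreated replicate 3 (adjusted p from 0.0597 to 0.117). Its call was also lost with normexp, quantile normalization, median centring, no filter on dim probes, the mean of its probes and the slide as a block (adjusted p = 0.0691, 0.0668, 0.0547, 0.0807, 0.0508 and 0.0801). The cold transcription factors had 0 calls by limma, 10 members at an unadjusted p below 0.05 and 6 lower adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.0101, and adjusted p = 0.846 with an estimated correlation). CBF1 was at -1.17 ± 0.41 (adjusted p = 0.176), CBF2 at -1.34 ± 0.36 (adjusted p = 0.0909) and CBF3 at -0.99 ± 0.23 (adjusted p = 0.0578). All of these CBF genes were called higher in untreated axe1-5 and were not called between the genotypes after cold. The ABA list had 1 lower gene, LEA14, and 3 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 8.13e-05, and adjusted p = 0.831 with an estimated correlation). The floral organ list had 1 gene with a more positive response, SEP3, over all genes and adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.831 with an estimated correlation). Its median was 0.88, or 0.84 with dim genes at their bounds, and it did not pass without DR5 untreated replicate 2 (median 0.58, adjusted p = 0.0639) or axe1-5 cold replicate 1 (adjusted p = 0.072). LEA14 at -0.50 ± 0.09 (adjusted p = 0.0313) lost its call on leaving out any of 8 arrays, DR5 untreated replicates 1 and 3, DR5 cold replicates 2 and 3, axe1-5 untreated replicates 1 and 2 and axe1-5 cold replicates 2 and 3 (adjusted p from 0.0579 to 0.0871). LEA14 was also not called with normexp (adjusted p = 0.118), with no filter on dim probes (adjusted p = 0.0538) or with the slide as a block (adjusted p = 0.0658). SEP3 at 1.54 ± 0.33 (adjusted p = 0.0484) lost its call on leaving out any array but DR5 untreated replicate 2 (adjusted p from 0.0502 to 0.116). The same held with no filter on dim probes (adjusted p = 0.0771), with the mean of its probes (adjusted p = 0.0544) and with the slide as a block (adjusted p = 0.0722).

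For the remaining lists the difference of the responses did not pass, with adjusted p from 0.0748 for DNA methylation and silencing and 0.0959 for heat shock to 0.99 for photosynthesis. Called members were HDA6 among the histone deacetylases and FLC in the flowering time and silenced lists. Limma called 0 in the other lists, which had between 0 (root markers) and 5 (jasmonate, and DNA methylation and silencing) members at an unadjusted p below 0.05. Adjusted over the list alone, heat shock and flavonoid had 2 more positive each and DNA methylation and silencing 1. Silenced loci and jasmonate had 2 more negative each, and salicylate, the clock, cell cycle and growth, flowering time and histone deacetylases 1 each. The difference for MAF4 was -0.20, for MAF5 -0.09, for KNAT1 0.13 and for KNAT2 -0.06, and none of these passed.

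The cold responses differed for 455 genes, 188 more positive and 267 more negative in axe1-5. Of these 81 were at least 2-fold, without genes dim in a group (fitted over all: 49 higher, 109 lower). At an unadjusted p below 0.05 there were 4090. Of the 455, 453 had one direction on all 3 slides, which calling on the same arrays largely fixes. The slide as a block gave 293. The 26 list shifts of the 5 comparisons that passed at the preset correlation all passed with this block. The count moved by over 1.5 times without DR5 untreated replicate 2 (701) or 3 (226) or DR5 cold replicate 1 (264), 2 (138) or 3 (202). It did so without axe1-5 untreated replicate 1 (135), 2 (176) or 3 (227), or axe1-5 cold replicate 2 (200). With normexp it was 277, without a filter 246 and with the authors' values 833. Without DR5 untreated replicate 1, the array apart on the third component, the counts of the 5 comparisons were 18224, 18662, 2975, 4313 and 323.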

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

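The tests of a sequence difference under the HDA6 probe, of a single array behind the floral difference, of the flower bud genes without AMS and of splits within slides were chosen only after the result was seen.

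A difference between the cold responses of axe1-5 and DR5, tested as the interaction of genotype and cold, was found for 455 genes. Other splits of the samples exchanged the genotypes within each treatment, after each gene's mean genotype difference was removed. Of 60 splits drawn from the 200 possible, only 1, the real one, called as many, and the highest count in the others was 1. This share is the smallest that 60 splits can give, and it argues against chance as the source of a count of this size. The mean difference came from the real genotypes, so its removal sets the interaction to 0 where all genotypes of 1 treatment are exchanged. It also damps a real interaction in other splits. Group and array position stay inseparable in these splits. The count of 455 itself ran from 135 to 701 without single arrays and was 293 with the slide as a block. With that block, 32 splits exchanged genotypes only between arrays of one treatment on one slide. Of these only 1, the real one, called as many as 293, and the highest count in the others was 0. That share of 1 in 32 argues against chance there too, with the same limits. For the 4 comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real counts there were 18452, 18553, 3704 and 3934, and the highest counts of the other splits 0, 0, 0 and 1.

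HDA6 rose with cold by 1.38 in DR5 and 0.37 in axe1-5, an interaction of -1.01. A sequence difference under the probe as the whole cause is argued against by the untreated plants, where the genotypes differed by -0.084 with the same probe. A scaling between arrays is argued against by the other settings, where the interaction closest to 0 was -0.93. What stays open is whether the mutant allele changes the stability of its own transcript or the cold response of the gene, and neither was tested. A difference in the cold response of HDA6 between these genotypes may therefore be biological, as a hypothesis found and tested on the same arrays.

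SEP3 changed by -0.58 in DR5 and 0.97 in axe1-5 with cold, an interaction of 1.54 that stands beside the lower floral organ genes of untreated axe1-5. A single array is argued against as the whole cause, since at least 6 of the 7 genes stayed lower by 0.5 or more whichever of the 6 untreated arrays was left out. The number called fell from 5 to 2 without DR5 untreated replicate 2 or 3 or axe1-5 untreated replicate 1, and to 3 without axe1-5 untreated replicate 2. Fewer flower buds in the untreated mutant samples cannot be told apart from lower expression within them, because 10 other flower bud genes had a median of -0.30, neither below -0.5 nor above -0.3 by more than its spread. AMS was not well above background on any untreated array. The 9 others had a median of -0.2999, 8 below 0 and 1 above (-0.90 to 0.58), with SHP1 lower (-0.69) and SPT higher. Camera p was 0.24, or 0.116 without AMS. The genotype itself stays open, untested.

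Interactions of the other genes singled out by the same test, without explanation, were in the positive direction 4.43 for BIP3, 3.13 for the LEA gene AT3G53040, 2.61 for AT4G21730 and 1.68 for AT5G16980. They were also 1.67 for UGT73C1 (AT2G36750), 1.57 for the transposable element gene AT2G12490, 1.14 for AT5G26270 and 0.98 for AT4G16960. In the negative direction they were -2.66 for AT5G41750, -1.95 for CBF4 (AT5G51990), -1.86 for BFT, -1.75 for DUF4, -1.74 for AT1G67856, -1.64 for the LEA gene AT3G15670, -1.37 for FLC, -0.70 for AT2G22590, -0.50 for LEA14 and -0.41 for COR15A. Each of these had one direction on 3 of 3 slides, which calling on the same arrays largely fixes. With the slide as a block AT1G67856 (adjusted p = 0.0511), LEA14 (0.0658), AT3G53040 (0.066), AT2G12490 (0.067), AT3G15670 (0.0722), AT2G22590 (0.0747) and COR15A (0.0801) were no longer called, nor was SEP3 (0.0722). The largest adjusted p on leaving out an array stayed below the threshold for BIP3 (0.0448), AT4G21730 (0.0396), AT5G16980 (0.00393), AT5G41750 (0.0135), DUF4 (0.00701), FLC (0.0483) and AT4G16960 (0.0171). The call of CBF4 ended without DR5 cold replicate 2 or axe1-5 untreated replicate 1 or 2 (adjusted p up to 0.0559). That of AT1G67856 ended without DR5 cold replicate 2 or 3 or axe1-5 untreated replicate 1 or 2 (adjusted p up to 0.0567). BFT and AT5G26270 lost theirs on leaving out any of 7 arrays (adjusted p up to 0.0807 and 0.0791) and AT3G53040 any of 8 (0.0903). It was any of 9 for AT2G12490 and UGT73C1 (0.0854 and 0.0926), any of 10 for AT3G15670 (0.0795) and any of 11 for AT2G22590 (0.101). Normexp ended the calls of AT2G12490 (0.86, adjusted p = 0.056), AT3G15670 (-0.98, adjusted p = 0.102), AT5G26270 (adjusted p = 0.0702), AT2G22590 (adjusted p = 0.0846), LEA14 (adjusted p = 0.118) and COR15A (adjusted p = 0.0691), and gave -0.92 for DUF4, still called. Without a filter on dim probes AT5G26270 (adjusted p = 0.053), LEA14 (0.0538), AT2G12490 (0.0552), AT3G53040 (0.0569), AT3G15670 (0.0579), UGT73C1 (0.0624), AT2G22590 (0.0691), SEP3 (0.0771) and COR15A (0.0807) were not called. Quantile normalization ended the calls of COR15A (adjusted p = 0.0668), AT2G22590 (adjusted p = 0.0904) and AT5G26270 (0.71, adjusted p = 0.0952), median centring that of COR15A (adjusted p = 0.0547). The mean of a gene's probes ended those of COR15A (adjusted p = 0.0508) and SEP3 (adjusted p = 0.0544) and gave 0.38 for AT4G16960 (adjusted p = 0.0486).

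Interactions of genes not well above background on every array passed the test with an adjusted p of 6.39e-07 for AT2G14970, 0.00022 for AT5G45095, 0.0039 for AT3G31373, 0.00524 for AT3G29572, 0.0108 for AT4G07965 and 0.0181 for AT3G12850, with no fold given.

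Of 2044 probes without a locus, which enter no gene comparison, 72 were higher by a fitted 2-fold or more in untreated axe1-5 and 6 lower.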

How the results depend on the processing

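No alternative was chosen after the result was seen. The count of genes whose cold responses differ, 455, became 277 with normexp, 246 without a filter on dim probes, 833 with the authors' processed values, 59 at an adjusted p below 0.01 and 135 to 701 on leaving out single arrays. At an adjusted p below 0.01 the genotype counts were 1774 untreated and 1741 after cold, and the count after cold was 2462 in a fit of the 2 groups alone. Leaving out single arrays gave 17834 to 18544 genes for cold in DR5, 17954 to 18662 for cold in axe1-5, 2302 to 3874 for the genotypes untreated and 2310 to 4313 after cold. It gave -1.14 to -0.90 for the HDA6 interaction (-1.03 to -0.93 under the other settings) and 24 to 30 list shifts. Of 26 list shifts of 105 tests, 2 passed with an estimated correlation, those of transposable element genes between the genotypes. The correlation of the cold responses was 0.972 with normexp, 0.925 without a filter, 0.974 over probes well above background on all arrays, 0.966 with the authors' processed values, 0.964 over genes called in either comparison and 0.953 to 0.963 without single arrays. The correlation of the genotype differences was 0.757 with normexp, 0.789 with quantile normalization, 0.679 without a filter, 0.664 over probes well above background on all arrays, 0.746 with the authors' processed values, 0.860 over genes called in either comparison and 0.774 to 0.815 without single arrays. Of 314 calls of named genes, 273 to 302 held without single arrays, 247 at an adjusted p below 0.01 and 286 with normexp. With quantile normalization 307 held, 298 with median centring, 295 without a filter, 303 with the mean of a gene's probes, 305 with the authors' processed values, and 239 of the 240 measured on all arrays. With the slide as a random block (residual correlation 0.0590) or an intensity trend, 314 held.

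Among named values that turned their sign, SDC alone was called, for cold in DR5, where the authors' processed values gave 0 at their floor, as they did for AtMu1 there and for KNATM between the genotypes after cold. KNATM there was -0.044 with normexp and -0.060 with quantile normalization. The FUS3 interaction was -0.35 with normexp, -0.15 with the mean of probes and -0.75 with the authors' processed values, and that of KNAT2 0.045 with normexp. Between the genotypes after cold, CBF1 was -0.037 with quantile normalization, DEAR1 -0.017 and RAP2.1 -0.0092 with median centring, and ICE1 0.035 with the mean of probes. For cold in DR5, CZF1 was 0.18 and DEAR1 0.10 with median centring, which adds one shift to every gene. The RAP2.1 interaction was -0.017 with median centring and -0.0078 with the mean of probes. Without single arrays, AtMu1 ran from -0.27 to 0.25 for cold in DR5, -0.045 to 0.97 for cold in axe1-5 and -0.10 to 0.92 for the interaction. Between the genotypes after cold, CBF2 ran from -0.092 to 0.040, DEAR1 from -0.014 to 0.12, KNAT1 from -0.11 to 0.0067 and KNATM from -0.14 to 0.34, and between them untreated RAP2.6 from -0.50 to 0.036. For cold in DR5, CZF1 ran from -0.19 to 0.10 and DEAR1 from -0.21 to 0.013. The interactions of FUS3 ran from -0.060 to 0.30, KNAT2 from -0.13 to 0.033, MAF5 from -0.43 to 0.46 and RAP2.1 from -0.050 to 0.055. For the other changes the cause was not tested.

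Arrays with one replicate number shared a slide, but their deviations from the group means did not go together in most pairs. The 18 pairs of arrays with one number had residual correlations of -0.178 to 0.197, 4 of them over 0.1, and 5 of 12 arrays lay closest to an array with their own number. The replicate block gave 18587, 18724, 3865, 4125 and 293 genes and held 299 of the 314 named calls. Signal over background limits 1279 genes that were not well above background in at least 1 group to bounds there.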

Other observations

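The lists of flower bud and unfolded protein response genes were chosen only after the data had been seen, the tests of the patterns below before their results, except the count of pairs with no annotated gene between them, chosen after.

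Unfolded protein response genes, 15 of which were tested, moved both ways with cold, 8 higher and 4 lower in DR5 and 8 higher and 3 lower in axe1-5. The chaperone genes of the endoplasmic reticulum BIP1, BIP2 and CNX1 rose by 1.41 ± 0.10, 1.08 ± 0.09 and 0.97 ± 0.09 in DR5 and by 1.68, 1.48 and 1.3 in axe1-5, UTR1 rose by 0.82 and 1.12, and DER1 was at -1.12 and -0.94. Among flower bud genes, FUL rose by 2.62 ± 0.26 in DR5 and 2.34 in axe1-5 and CAL by 1.61 ± 0.41 and 1.77, the latter from a level well above background on 1 of 3 arrays, while SPL3 was at -2.27 ± 0.15 and -2.02 and SHP1 at -1.22 ± 0.16 and -1.12. Single arrays were not left out for these genes.

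A hypothesis from the BIP3 interaction is that a wider unfolded protein response to cold may be stronger in axe1-5. The other 15 genes had a median interaction of 0.24, 12 of them above 0, and 1, ERDJ3A at 0.95, was called. The camera p was 0.00105 at the preset correlation and 0.121 with an estimated correlation, so the test leaves the hypothesis open.

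Neighbouring loci were often higher together in axe1-5. Among 21920 placed genes, 447 were higher by a fitted 2-fold or more in both conditions, 68 of them transposable element genes. The 447 formed 39 adjacent pairs among the measured genes, 18 with a transposable element gene. In the reference annotation 21 of the 39, such as MAF4 with MAF5, had no other gene starting between them, and the other 18, such as FUS3 with AT3G26800, did. Shuffles (10000 in blocks of 100 measured genes) argue against regional density on that scale only. Their median was 18 pairs and their highest 33, or 8 and 20 with no gene between (permutation p = 1e-04, the smallest possible). Probes of 3 of 39 pairs (7.69%) shared 20 bases, but matches to the neighbour's transcript were not tested. Finer-scale density and cross-hybridisation stay open, as do transcripts (not tested) reading through into the next locus or antisense to it. A shared release from silencing in axe1-5 is only a hypothesis.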
